A study of Homo sapiens with 15 samples.

How the data were processed

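RNA from 11 subcutaneous xenografts of HuH7, a human hepatocellular carcinoma cell line, and from 4 HuH7 cell cultures was hybridized to Clariom S human arrays, 1 array per sample. The tumours grew in female nude mice and had reached 100 mm3 when, per the labels' protocols, the animals were assigned at random to zinc acexamate (ZAC) at 150 mg/kg or to vehicle. Tumours were taken 1 hour after the last dose. The groups held 5 vehicle and 6 ZAC tumours, each with its own animal number in the title, and no number occurred in both groups. The cell arrays were D0, labelled as untreated, and D100, D150 and D250, labelled as treated with zinc acexamate. The meaning and unit of the numbers 100, 150 and 250 in those titles, the time of exposure and any scan date or batch are not given in the sources used here, so no dose is attached to them.

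The values are log2 expression per probe set, processed with RMA (background correction, normalization between arrays and summary of probes) by the authors, per the submitters' processing notes. The version of RMA, and whether tumours and cells were normalized in 1 run, are not given in the sources used here. The table held 24351 probe sets on 15 arrays and no column without a sample. A gene was named through the platform table, in which 17709 probe sets had 1 gene symbol, 0 had several and 6642 had none, and 0 symbols had to be updated through the reference list of genes. For the 20 genes with several probe sets, the one with the highest mean over all arrays stood for the gene, which left 17687 genes. No coordinates are printed, since the build is not given. RMA is built to make the distributions of arrays alike, so a change of the total RNA per cell would not be seen. The median of named genes lay between 6.94 and 7.08 on every array. Mouse transcripts from stroma reach a human array only by cross-hybridisation. Metallothionein, histone, heat shock 70 and other near-identical family members share sequence, so a value given for one copy is uncertain between copies. The precision is limited by the number of arrays.

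Tumours were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes without trend), 2-sided, with Benjamini-Hochberg adjustment over all 17687 genes and a threshold of 0.05. On simulated data with the tumours' own spread, this step recovered 81% of 100 genes changed by 1 on the log2 scale. It recovered 99% of 100 genes changed by 2, with 6 false calls among the genes left unchanged. The simulated genes varied independently, with equal spread in both groups. With fewer changed genes the adjustment is stricter, so a count of 0 in the real tumours does not exclude changes of this size. Lists of genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it, and the mean of a list per tumour was compared by an exact permutation test over all 462 splits of 11 tumours into 5 and 6. A list score is the mean over its genes of the deviation from that gene's mean over the 11 tumours. The p-values of limma, fry and the permutation tests of tumours measure the spread between animals. Camera with the preset correlation takes the genes of a list as nearly independent. Its p-values can therefore be far lower than the spread between animals alone would give.

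The cell arrays have 1 sample per group, so the differences between them are given without a p-value. The limma fits that take treated arrays as replicates, use a slope on the title number or borrow the tumours' spread appear as counts and rest on those assumptions. A gene counted as changed when it differed from D0 by at least 1 on the log2 scale, one way, on all 3 treated arrays. The median difference of a list was placed among 10000 random lists of the same size matched on mean expression. Because D0 serves all 3 differences, 100 sets of unchanged arrays with the tumours' spread were simulated. Tumour and cell effects were correlated across genes, with the tumour labels permuted over all 462 splits, a test added after the data were seen. Their difference was fitted as an interaction term in limma with the 3 treated cell arrays taken as replicates. Vehicle tumours were set against D0 by a difference of at least 2 in the means with all 5 tumours on one side.

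The design, alternatives, lists and rule for named genes were fixed before the data were examined. The rule took, for tumours, the 12 largest rises and falls among genes that passed and otherwise the genes with the lowest unadjusted p up to 12 each way. It took the 12 largest rises and falls among cell genes past the rule, and 8 each way between tumours and cells. From every list it took up to 4 members per comparison, and all metallothioneins and zinc transporters. Genes that cannot be named, XIST and Y-linked genes were left out. The 29 lists of processes and 10 lists of other cell types held 747 genes, of which 666 were measured. The process lists were metallothioneins, zinc transporters, heat shock response, NRF2 antioxidant genes, integrated stress response, ER chaperones, p53 targets, apoptosis regulators, S phase, mitosis, DNA repair, immediate early genes, hypoxia and glycolysis, hepatocyte genes, fetal liver genes, acute phase genes, beta-catenin targets, EMT genes, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, respiratory chain, ferroptosis and iron, autophagy and lysosome, interferon response, NF-kappaB genes, TGF-beta targets, ribosomal proteins and histones. The others were markers of endothelium, fibroblasts, smooth muscle, macrophages, neutrophils, lymphoid cells, erythroid cells, adipocytes, skeletal muscle and keratinocytes. Alternatives covered moderation, array weights, renormalization, median centring, leaving out the 30% dimmest genes, means of probe sets, a stroma covariate made of 4 marker lists, other thresholds, and each tumour left out in turn. Figures were drawn with matplotlib.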

Results

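The series measured gene expression in HuH7 liver cancer cells, grown as xenografts in mice or in culture, with and without zinc acexamate (ZAC), a zinc salt of acexamic acid. There were 5 vehicle tumours, 6 ZAC tumours, 1 untreated culture (D0) and 3 treated cultures (D100, D150 and D250). Correlations of array values across genes lay between 0.977 and 0.994 among tumours, between 0.980 and 0.993 among cell arrays, and between 0.939 and 0.972 for a tumour with a cell array. In a principal component analysis of the tumours, the first component held 31.8% of the variance and did not separate the groups (exact permutation p = 0.405). The second held 18.1% (exact permutation p = 0.0281).

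The first comparison asked what ZAC changed in the tumours. Metallothioneins, small cysteine-rich proteins that bind zinc, many of them induced by it, were higher as a group. The median log2 difference was 1.18, with 11 of 11 measured members higher. All 11 passed at an adjusted p under 0.05 when adjusted over the list alone, and 0 passed over all 17687 genes. Members share sequence, so these are not 11 separate results. MT1HL1 was dim, at 4.17 to 5.09 in the tumours. MT3 and MT4 were highest in ZAC tumour 4 (8.44 and 7.52), whose MT1E (12.56) lay within the vehicle range. In the treated cultures described below, MT3 and MT4 did not rise on every array, so they may not belong with the MT1 genes and MT2A. The log2 value of MT2A was 15.17 ± 0.17 (SD, n = 5) in vehicle and 16.24 ± 0.49 (SD, n = 6) in ZAC tumours, a 2.09-fold difference (95% CI 0.62 to 1.51 on the log2 scale), with 6 of 6 ZAC tumours above every vehicle tumour. MT1M differed by 2.10 (SE 0.54), MT1E by 1.39 (SE 0.40) and MT1F by 1.24 (SE 0.36), each with 5 of 6 ZAC tumours above every vehicle tumour. MT4 (1.10, SE 0.22) and MT3 (0.69, SE 0.17) were above in 6 of 6. A gene without any difference separates the groups completely in 2 of the 462 splits, a share of 0.433%. The list passed camera (adjusted p = 1.4e-15) and fry (adjusted p = 0.0416). It did not pass with an estimated correlation (adjusted p = 0.0897). Nor did it pass in the exact permutation test of the list score (p = 0.00866, adjusted p = 0.169 over 39 lists). Its adjusted p over all alternatives lay between 3.43e-24 and 0.169.

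**Figure D1:**
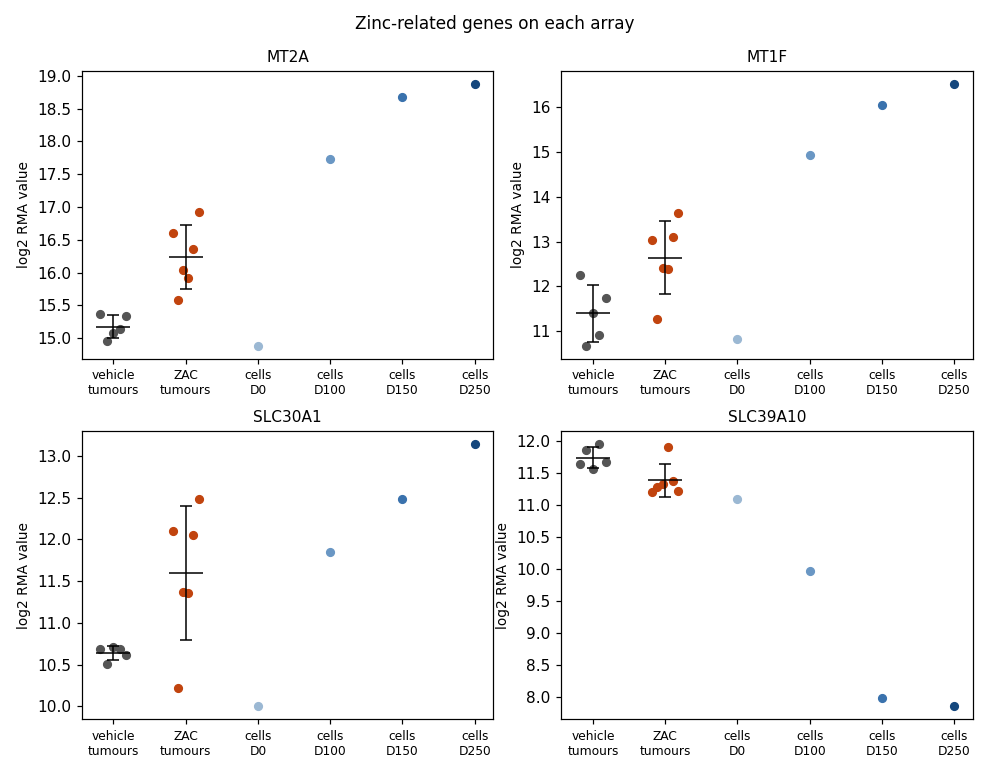
Log2 RMA values (vertical axes) of MT2A, MT1F, the zinc exporter SLC30A1 and the zinc importer SLC39A10 on each array, by group (horizontal axes); points are single arrays, and bars in the tumour groups are the mean and SD of 5 vehicle and 6 ZAC tumours. MT2A lay at 14.88 on D0 and at 17.73, 18.67 and 18.88 on D100, D150 and D250.

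Zinc transporters as a list of 26 genes did not move one way (median 0.01, camera adjusted p = 0.855). SLC30A1, which exports zinc from the cell and is induced with metallothioneins, differed by 0.95 (SE 0.30), with 5 of 6 ZAC tumours above every vehicle tumour and 1 below. SLC39A10, an importer, differed by -0.35 (SE 0.15), with 5 of 6 below every vehicle tumour. SLC39A5 (-0.65, SE 0.21) and SLC30A10 (-0.99, SE 0.34), a manganese exporter, were lower. MTF1, the zinc-sensing transcription factor of these promoters, differed by 0.02 (SE 0.18). None of these passed adjustment over all genes (limma adjusted p from 0.480 to 0.98) or over the list alone.

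Over all genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.449. At an unadjusted p under 0.05 there were 510 higher and 1066 lower genes, where 884 of either sign would come by chance. That split depended on scaling: 32.4% were higher as deposited, 47.8% after a second quantile normalization of the tumours and 50.6% after centring each array on its median. Besides MT2A, MT4, MT3, MT1M and MT1B, the genes with the lowest p among the rises were PSMG1, a chaperone of proteasome assembly (0.98, SE 0.23), ITGAE (0.82), UBLCP1 (0.78), SPATA24 (0.60), CCDC30 (0.60), EPHB1 (0.49) and PPP1R12A, a subunit of myosin phosphatase (0.47). None passed. Among the falls with the lowest p, which did not pass either, PPP1R3B, which directs a phosphatase to glycogen, differed by -1.26 (SE 0.24), HPN, the hepatocyte protease hepsin, by -1.03 (SE 0.18), BDH1, an enzyme of ketone bodies, by -0.85, EPHX2 by -0.72 and CPN2 by -0.62. PRKAB2, a subunit of AMP-activated kinase, differed by -0.99, DUSP18 by -0.95, LMBR1L by -1.09, DAB2 by -0.81, TRIO by -0.77, NOTCH2 by -0.76 and GATA4, a liver transcription factor, by -0.70. Of these 12 genes, 11 were below every vehicle tumour in 6 of 6 ZAC tumours, and BDH1 in 5 of 6. Because the 12 were taken for the lowest p over all genes, this separation follows largely from that choice. It is no further evidence for them, and the count of such genes over all genes is not given here. Without vehicle tumour 1, 5 genes passed as lower: PPP1R3B, HPN, PRKAB2, PLG and MYOF, each at an adjusted p of 0.0495. The adjusted p of HPN, PPP1R3B and PRKAB2 ranged up to 0.753 over the alternatives. MYOF was outside the fixed rule and is named after its values were seen.

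Of the 39 lists, camera called 11 in the tumours at an adjusted p under 0.05, and only metallothioneins passed fry. All 11 were lost with an estimated correlation. S phase and replication genes were higher (22 of 23 members, median 0.33, camera adjusted p = 2.22e-06; adjusted p = 0.66 with an estimated correlation), with SLBP at 0.86, PCNA at 0.74 and CCNE2 at 0.71. Without vehicle tumour 17 their mean difference was 0.16 instead of 0.40, and camera still called them (adjusted p = 0.0191). Leaving out vehicle tumour 1 gave a mean of 0.58. Hypoxia and glycolysis genes were lower (22 of 23, median -0.42, camera adjusted p = 0.000264; adjusted p = 0.66 with an estimated correlation), among them NDRG1 (-1.27), HK2 (-0.78) and VEGFA (-0.71), the vascular growth factor. Their mean difference was -0.26 instead of -0.40 without vehicle tumour 17. Without vehicle tumour 17 and ZAC tumour 4 together, an alternative chosen after the data were seen because these lay at the extremes of the second component and ZAC tumour 4 had the lowest metallothionein score of its group, the mean was -0.14 and hypoxia genes were no longer called (camera adjusted p = 0.225, with a range over alternatives from 3.39e-08 to 0.66). Fatty acid oxidation genes were lower (14 of 18, median -0.13; adjusted p = 0.228 with an estimated correlation), led by CPT1A, which carries fatty acids into mitochondria (-1.92, SE 0.52), PDK4 (-0.63) and ETFDH (-0.52). The exact permutation p of their score was 0.00649 (adjusted p = 0.169). Fatty acid synthesis and storage genes were lower in 14 of 16 (median -0.26; adjusted p = 0.619 with an estimated correlation), with CIDEB at -0.82 and PNPLA3 at -0.50. Hepatocyte genes were lower in 22 of 29 (median -0.20, mean -0.21, camera adjusted p = 0.66 with an estimated correlation). Their mean was -0.35 over the 20 left without the 30% dimmest genes. APOC3 differed by -0.99 and the fibrinogen genes FGA by -0.88 and FGB by -0.58. Adjusted over the list alone, 1 fatty acid oxidation gene (CPT1A) and 1 hepatocyte gene (FGA) passed as lower, and 0 genes passed in the lists of S phase, hypoxia and fatty acid synthesis.

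**Figure D2:**
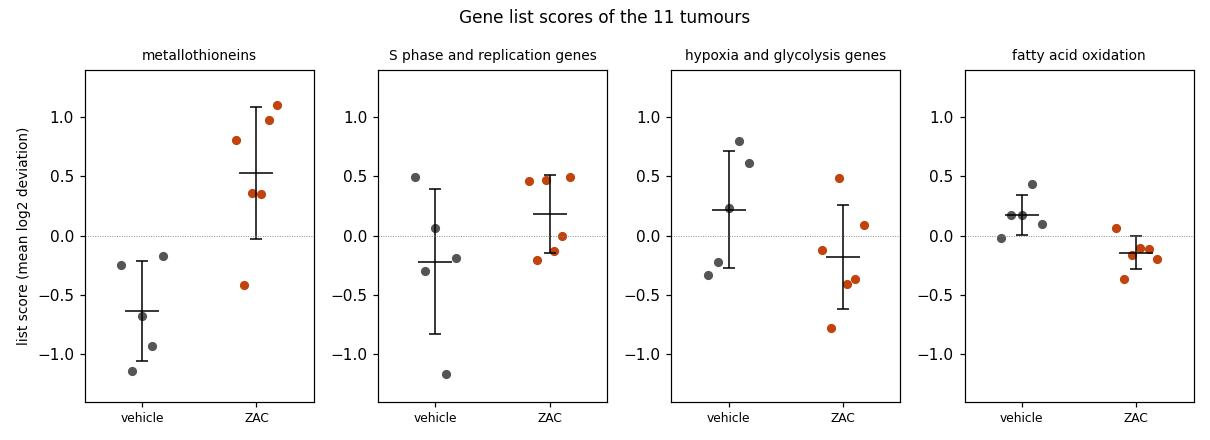
Scores of 4 gene lists in the 11 tumours; the vertical axis is the mean log2 deviation of the list's genes from their mean over all tumours, points are tumours, and bars are the mean and SD of 5 vehicle and 6 ZAC tumours. The metallothionein score of ZAC tumour 4, at -0.42, lay within the vehicle range, and the S phase score of vehicle tumour 17 was -1.17.

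Camera called 5 further lists. Histones had a median of -0.23 (17 of 19 lower), autophagy and lysosome genes of -0.17 (16 of 20 lower, CTSB at -0.58), cholesterol synthesis of -0.16 (13 of 18 lower, SREBF2 at -0.62), mitosis genes of 0.20 (24 of 28 higher) and NRF2 antioxidant genes of 0.25 (19 of 23 higher). Their adjusted p with an estimated correlation lay between 0.619 and 0.789. In the NRF2 list the members with the lowest p among those that differed downwards were ABCC3 (-1.12) and EPHX1 (-0.65). Adjusted over the list alone, 0 members passed in these 5 lists. Leaving out 1 tumour ended the camera call for mitosis genes (vehicle 7, 17 or 19, ZAC 2, 6 or 23), cholesterol synthesis (vehicle 1, 14 or 19, ZAC 4, 6 or 12), NRF2 genes (vehicle 7 or 17, ZAC 6 or 23), hepatocyte genes (vehicle 19, ZAC 23), autophagy genes (vehicle 7, ZAC 4) and histones (ZAC 12). The mean difference of mitosis genes, 0.20, was 0.07, 0.10, 0.10 and 0.12 without vehicle 17, vehicle 7, ZAC 6 or ZAC 2, and 0.34, 0.31 and 0.30 without vehicle 1, vehicle 14 or ZAC 10. That of NRF2 genes, 0.22, was 0.11, 0.13 and 0.33 without ZAC 23, 6 or 10, that of cholesterol genes, -0.16, was -0.05 without ZAC 4, and that of histones, -0.22, was -0.14 without ZAC 12. Without vehicle 17 and ZAC 4 together, camera called 8 lists, and mitosis (adjusted p = 0.0612), cholesterol (0.316) and autophagy genes (0.154) were not among them. Leaving out the 30% dimmest genes ended the calls of cholesterol (adjusted p = 0.117) and autophagy genes (0.0783), and 9 of the 11 lists were still called.

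The remaining process lists did not pass camera (adjusted p from 0.082 to 0.90). Their median log2 differences were 0.12 for ribosomal proteins, 0.14 for heat shock, -0.04 for NF-kappaB genes, -0.08 for EMT genes, 0.17 for DNA repair, -0.09 for ER chaperones, -0.05 for beta-catenin targets, -0.13 for p53 targets and -0.05 for fetal liver genes. They were -0.17 for acute phase genes, 0.01 for the respiratory chain, 0.02 for ferroptosis and iron genes, -0.05 for the integrated stress response, 0.01 for immediate early genes, 0.05 for the interferon response, 0.02 for apoptosis regulators and 0.07 for TGF-beta targets. Adjusted over the list alone, 1 gene each passed as lower among ER chaperones (HERPUD1, -0.89), p53 targets (CDKN1A, -0.67) and immediate early genes (FOSL2, -0.78), and 0 in the other process lists that camera did not call. Mean and median had opposite signs for ferroptosis, stress response, immediate early and apoptosis genes and for zinc transporters, and camera's direction differed from both for TGF-beta targets. The medians of stress response and ferroptosis genes, and of the macrophage and keratinocyte markers, changed sign with rescaling of the arrays. Markers of other cell types did not pass either (adjusted p from 0.084 to 0.86). Their medians were 0.04 for endothelium, -0.08 for fibroblasts, -0.06 for smooth muscle, 0.04 for macrophages, 0.20 for neutrophils, 0.16 for lymphoid cells, 0.13 for erythroid cells, 0.07 for adipocytes, -0.18 for skeletal muscle (1 gene, TTN at -0.61, passed as lower when adjusted over the list alone) and -0.04 for keratinocytes.

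The second comparison set the treated HuH7 cultures against the untreated one. Metallothioneins were far higher on every treated array: 8 of 11 measured members lay at least 1 above D0 on all 3. MT1M lay 3.65, 5.64 and 5.80 above D0 on D100, D150 and D250, MT1F 4.11, 5.22 and 5.69, MT1H 2.97, 5.20 and 5.77, and MT2A 2.85, 3.79 and 4.0. MT1E, MT1G, MT1X, MT1B and the related MT1L and MT1IP followed, while MT3 stayed within 0.26 of D0 and MT4 lay at -0.09, 1.14 and 0.22. MT2A was the brightest named gene on D150 and D250 and rank 259 on D0. SLC30A1 was higher by 1.85, 2.48 and 3.14, and SLC39A10 lower by -1.13, -3.10 and -3.23. The glycine transporter SLC6A9 was higher by 1.31, 1.25 and 2.31. In all, 22 genes were at least 1 higher and 10 at least 1 lower on all 3 arrays. The lower ones besides SLC39A10 were KRT23 (-1.55, -1.36 and -2.33), TFF1 (-1.13, -1.11 and -2.34), SERPINA6, the plasma carrier of cortisol (-1.18, -1.09 and -2.04), TAX1BP3, SAMD3, SH3BGRL, TEKT3, LARGE2 and UPK1B. These differences have no replicate check. Unchanged arrays with the tumours' spread would give 56.2 higher and 56.8 lower genes through the shared D0, against 0.0588 and 0.062 for independent lists. That spread need not be the spread between cultures. It gave a covariance of 0.118 for the differences of D100 and D150, where 0.080 was observed. The simulation therefore cannot say how many genes unchanged cultures would give, and the counts stand without a test. After centring each array on its median they were 17 and 13, or 56.7% higher in place of 68.8%.

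D250 differed most. It had 903 genes at least 1 above and 946 at least 1 below D0, against 151 and 207 on D100 and 135 and 99 on D150. The correlation across genes of the differences from the common D0 was 0.50 for D100 with D150, 0.52 for D100 with D250 and 0.32 for D150 with D250, where unchanged arrays sharing D0 give 0.50. The covariances were 0.080, 0.140 and 0.078, where unchanged arrays with the tumours' spread give 0.118. With 1 D0 array the control could not be split.

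On D250, genes of cholesterol synthesis were higher in 18 of 18 (median 1.25, percentile 100 among matched random lists), including HMGCS1 (1.77) and CYP51A1 (1.67). Integrated stress response genes had a median of 0.91 (percentile 100), with ATF3, a stress-induced transcription factor, at 4.15, STC2 at 2.37 and CHAC1 at 1.83. Immediate early genes had a median of 0.80 (percentile 100), with JUN at 3.01 and DUSP1 at 2.45. Autophagy and lysosome genes had a median of 0.59, with GABARAPL1 at 2.23, and EMT genes of 0.55, with CDH2 at 1.14. S phase genes were lower in 23 of 23 (median -1.08, percentile 0), with GINS2 at -1.98 and PCNA at -1.97, while mitosis genes had a median of 0.14. Respiratory chain genes had a median of -0.82 (percentile 0), with SDHA at -1.19. On D100 the medians of the S phase and cholesterol lists were -0.08 and -0.04, and on D150 0.11 and 0.05, the last of which was negative after both rescalings. The stress response list was at 0.16 on D100 and at 0.26 on D150 (20 of 25 higher, percentile 99.7). Markers of keratinocytes, another cell type, had a median of 0.41 on D250 (6 of 7 higher, percentile 99.6). Histones stood apart on D100 instead (median 0.71, percentile 100), where H4C1 lay 1.49 and H3C10 1.35 above D0. Hepatocyte genes had medians of -0.21, -0.10 and -0.22 on the 3 arrays, and acute phase genes of -0.12, -0.27 and -0.05, with 7 of 16 higher on D250. Among the latter, C3 lay at -2.54, -0.50 and -3.26 and A2M at 0.50, -0.03 and 1.07.

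**Figure D3:**
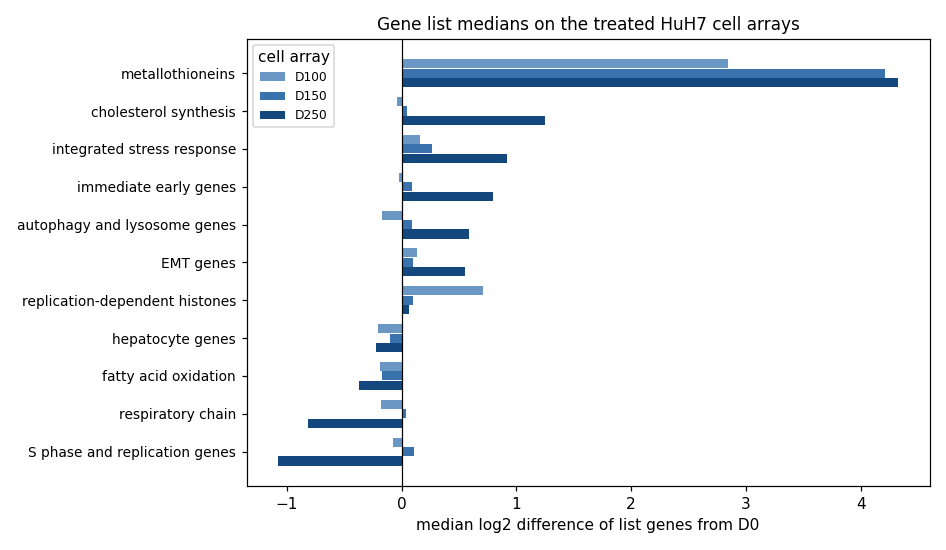
Median log2 difference from D0 (horizontal axis) of the genes of 11 lists (vertical axis) on D100, D150 and D250, 1 array each. Metallothionein medians were 2.85, 4.21 and 4.33, and cholesterol synthesis, stress response and S phase genes stood away from 0 on D250, with medians of 1.25, 0.91 and -1.08.

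The third comparison asked whether tumours and cells changed alike. Across genes, which are not independent replicates, the tumour difference and the mean cell difference correlated at r = -0.22 and rho = -0.26, and 41.3% of genes had the same sign. No array was shared by both. Permuting the tumour labels gave an r as large in 40 of 462 splits (exact permutation p = 0.0866, adjusted p = 0.363 over the 5 correlations computed). By array, r was -0.216 for D100, -0.0251 for D150 (exact permutation p = 0.900) and -0.233 for D250 (exact permutation p = 0.225). CPT1A differed by -1.92 in tumours and by 0.85, 0.60 and 1.86 in cells, and JUN by -0.80 in tumours and 0.81, 0.35 and 3.01 in cells. These are examples of opposite signs. SLC30A1 (0.95 in tumours) and SLC39A10 (-0.35 in tumours) moved the same way in both, as did all 10 metallothionein symbols past the cell rule. The interaction term of limma passed for 0 genes at an adjusted p under 0.05 (lowest 0.236), with 1235 at an unadjusted p under 0.05. It rests on the 3 treated arrays as replicates. The difference between D250 minus D0 and the tumour change was 2.93 for MT2A, 4.45 for MT1F and -2.88 for SLC39A10, and 150 genes passed with D250 as the only treated array. That fit takes its spread from the tumours and holds no variation between cultures, so its count is no test of a difference between tumours and cells.

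The last comparison set the 5 vehicle tumours against D0, 1 culture. There were 411 genes at least 2 higher and 233 at least 2 lower with all 5 tumours on one side. Whether tumours and cells were normalized together is not given in the sources used here, and separate normalization would enter each of these differences. Hypoxia and glycolysis genes were higher in 22 of 23 (median 1.77, percentile 100), with NDRG1 at 5.55, PDK1 at 3.81 and ALDOC at 2.65. Hepatocyte genes were higher in 17 of 29 (median 0.14, percentile 91.5). APOC3 was higher by 3.42, ARG1 by 3.77 and PLG, plasminogen, by 6.0. AQP10, a water and glycerol channel, was higher by 6.60, CD3G by 5.62, GCNT1 by 5.59, CDHR5 by 5.50, DEPTOR, an inhibitor of the mTOR kinase, by 5.31 and PRRX1 by 5.29. Fibroblast and matrix markers had a median of 0.54 (percentile 99.9), with COL1A2 at 3.56 and SPARC at 2.80 but LUM at -3.00. S phase genes were lower in 23 of 23 (median -1.56, percentile 0), with CDT1 at -3.38, and histones in 18 of 19 (median -1.07), with H3C1 at -2.71. Stress response genes (median -0.82), heat shock genes (-0.70), NRF2 genes (-0.70) and mitosis genes (-0.67) were lower, including CHAC1 (-3.15), BAG3 (-2.95) and CDC20 (-2.82). In the NRF2 list 7 of 23 were higher, and 3 passed the rule as higher against 2 as lower. The BMP and TGF-beta responsive ID1 and ID3 were lower by -5.41 and -5.25, SPP1 by -5.04, MLLT11 by -5.03, the WNT antagonist DKK1 by -4.95, CDKN2A by -4.52, SLC1A3 by -4.23 and THBS4 by -4.19. With 1 culture, this comparison has no replicates on the cell side.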

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

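The tests here follow rules set before the data were examined, and none was chosen after its result was seen. Each list score, named tumour gene and zinc-related gene was searched for a tumour far from the rest of its group, 190 searches in which chance gives about 9.5. There were 14, given as the gap to the nearest tumour divided by the range of the group. No technical or biological explanation was tested for them. In ZAC tumour 4, the zinc transporter score was lowest (gap 0.6253), as was SLC39A1 (0.657). ZAC tumour 10 was lowest in the heat shock score (0.721) and highest in SLC39A10 (0.750). ZAC tumour 23 was highest in the neutrophil marker score (0.664) and lowest in PRKAB2 (0.823) and SLC30A3 (0.735). ZAC tumour 6 was lowest in the skeletal muscle score (0.684) and highest in SLC30A7 (0.747). Vehicle tumour 17 was lowest in EPHB1 (0.844) and SLC39A1 (0.743) and highest in SLC30A4 (0.893). Vehicle tumour 14 was highest in the skeletal muscle score (0.809), and vehicle tumour 1 was lowest in the ferroptosis and iron score (0.729).

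Among the 3188 transcript probe sets without a gene symbol, which no comparison used, 2 lay at least 1 above D0 on all 3 treated cell arrays and 4 at least 1 below. One of the 2, chosen after its values were seen, lay 2.91 above D0 on D100 and 4.06 on D250, and its mean was 13.72 in vehicle and 14.94 in ZAC tumours.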

How the results depend on the processing

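The alternatives were fixed before the data were examined, except those named here as added later, after the data were seen. The count of tumour genes stayed at 0 higher and 0 lower under other moderation, array weights, both rescalings, the filter on dim genes, means of probe sets, the stroma covariate and the 1.5-fold limit. At an unadjusted p under 0.05 it was 510 and 1066, and 94 and 299 with at least 1.5-fold, because nothing is then adjusted. Leaving out 1 tumour gave 0 higher and 0 to 5 lower genes, the 5 without vehicle tumour 1. Without vehicle tumour 17 and ZAC tumour 4 together, added later, it was 0 and 0, 8 lists were called, and hypoxia (adjusted p = 0.225), mitosis, cholesterol and autophagy genes were not. The changes of 26 named tumour and zinc genes kept their direction under the alternatives of moderation, weights, scaling, probe sets and stroma and without each tumour, as did all but CCDC30 and EPHB1, which it removed, under the filter; 463 of these values stayed on their side of the threshold and 3 passed it. The 11 called lists became 0 with an estimated correlation, 1 with fry and 0 in the exact permutation test. They were 8 to 12 without 1 tumour and 11 without the 30% dimmest genes, 9 of them shared, with cholesterol (adjusted p = 0.117) and autophagy genes (0.0783) lost. The metallothionein difference, 1.16 on average, stayed between 1.04 and 1.35 without 1 tumour. It lost its call with an estimated correlation and in the exact test, at an average of 1.16 in both. The cell counts of 22 and 10 became 200 and 153 at 1.5-fold, 903 and 946 on D250 alone, 137 and 101 on the mean of the 3 arrays, and 0 and 0 in limma with the treated arrays as replicates (396 genes at an unadjusted p under 0.05) or with a slope on the title number (1802). On D100 and D150 alone, added later, they were 33 and 31. Lists outside the central 95% of random lists in cells numbered 13, and 6 on the mean of D100 and D150, added later. The correlation of tumour and cell effects lay between -0.24 and -0.14 without 1 tumour, with an exact permutation p of 0.0429 without vehicle tumour 19, and rho was -0.26 (exact permutation p = 0.0325). The range of that p over the alternatives was 0.0325 to 0.299. The interaction count of 0 became 150 with D250 alone, a fit without variation between cultures. Untreated tumours against D0 gave 411 and 233 genes, 1580 and 1713 at a difference of 1, and 269 higher genes over all tumours and cell arrays. Where no construction is named, the cause was not tested. No paired analysis was possible because the groups share no animal number. Signal over background limits dim genes, which array values cannot separate from background here.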

Other observations

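The stroma covariate, second normalizations, estimated correlation and left-out tumours were settings fixed before the data were examined, whose use as tests of an explanation was chosen only after the result was seen, as were the tests of probe set noise, SLC30A1, genes higher in tumours than in cells and splits for adjusted genes.

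On D250, p53 targets as a list had a median of 0.20 (percentile 85.8), with 10 of 17 higher, 4 of them by at least 1, and 2 lower by at least 1. They included TP53INP1, 3.93 above D0, GDF15, 3.58 above, and CDKN1A, the inhibitor of cyclin-dependent kinases, 1.90 above, while on D100 these lay at -0.43, -0.04 and 0.04; AEN lay at -1.35 on D250. Apoptosis regulators were higher in 10 of 18 (median 0.34), 3 of them by at least 1 and 2 lower by at least 1; BMF and PMAIP1 lay 2.09 and 1.81 above D0. The acute phase list had a median of -0.05 on D250 (percentile 32.7), with ORM1 and ORM2 at -2.49 and -2.33 and A2M at 1.07, and the neutrophil marker S100A9 lay at -4.53. In tumours, CDKN1A differed by -0.67 (SE 0.18) between ZAC and vehicle. CDKN1A passed when adjusted over the list alone and did not pass over all genes. The values in cells have no replicates.

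The metallothionein list was higher in ZAC tumours by 1.16 (SE 0.30) on average. After a second quantile normalization the difference was 1.20 (SE 0.28), so a remaining mismatch of array distributions did not make it. The tumour arrays had already been normalized by RMA, so this cannot decide on scaling at that step. The median change over the 3418 genes nearest in level to a list member was -0.0167, so these genes did not rise as a whole. They pool the neighbours of dim members such as MT1HL1 (4.17 to 5.09 in the tumours) with those of bright ones such as MT2A (14.95 to 16.92). This median therefore cannot decide on a rise limited to bright probe sets. With the stroma markers as covariate the difference was 1.15 (SE 0.30), but of its 4 marker lists only that of fibroblasts stood well above D0 (percentile 99.9, against 84.2 for smooth muscle, 45.9 for macrophages and 44.4 for endothelium), so what the covariate measures is uncertain and mouse stroma stays open. A response to the zinc in the drug is a candidate explanation, and chance also stays open, since the list was not called with an estimated correlation (adjusted p = 0.0897).

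The higher S phase score of ZAC tumours rested in large part on vehicle tumour 17: the difference was 0.16 without it instead of 0.40. Leaving out vehicle tumour 1 gave 0.58, the highest with 1 tumour left out. The hypoxia difference of -0.40 was -0.26 without vehicle tumour 17 and -0.28 without ZAC tumour 4. It was -0.54 without vehicle tumour 1 or ZAC tumour 6, the widest. Camera still called both lists without vehicle tumour 17 (adjusted p = 0.0191 for each). Genes of these lists varied together between tumours, and the adjusted p was 0.66 with an estimated correlation. That both scores follow one axis of tumour state could not be told apart from no relation: within groups, over 11 tumours, r was -0.13 (permutation p = 0.703, adjusted p = 0.703) and rho 0.14 (permutation p = 0.696, adjusted p = 0.703), and r was 0.75 over the 9 tumours left without vehicle tumours 17 and 1, so the sign rests on those. The treatment stays open as a cause.

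D250 stood far from the other cell arrays. After a second quantile normalization 1872 genes lay at least 1 from D0, against 1849 as deposited, so a remaining mismatch of array distributions did not make the count. The arrays had already been normalized by RMA, so this cannot decide on scaling at that step. Independent noise of probe sets is opposed by 9 of 39 list medians outside the central 99% of random lists on D250, where 0.39 would be. The 9 include keratinocyte markers. D150 had 5 such lists and D100 had 2, so this excess was not particular to D250. A difference in that culture or in its RNA and the treatment given in its label cannot be told apart with 1 array.

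In the ZAC tumours, SLC30A1 followed the metallothionein score. Over the 6 tumours r was 0.993 (exact permutation p = 0.00417, adjusted p = 0.0167) and rho 0.943 (exact permutation p = 0.0167, adjusted p = 0.0333), with 2 relations of this kind computed, each with r and rho. Without ZAC tumours 4 and 23, the 2 farthest from the median, r was 0.97 over 4. Both genes are known targets of the same zinc-sensing factor, so the hypothesis is that zinc exposure differed between tumours at the time of collection. ZAC tumour 4 had the lowest SLC30A1 (10.22, vehicle tumours 10.50 to 10.72) and the highest MT3 (8.44) and MT4 (7.52) of all tumours. A wrong label of that tumour was not tested.

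Whether tumours share a wider response of the cells stays open. All 10 metallothionein symbols past the cell rule were higher in ZAC tumours. Of the 22 other genes past it, SLC30A1 and SLC39A10 among them, 10 moved in tumours the way they did in cells, with a mean of 0.02 in that direction (exact permutation p = 0.866). No more genes passed the cell rule than unchanged arrays sharing D0 would give with the tumours' spread. That spread need not be the spread between cultures, which was not measured. With 1 array per group, it cannot be told which of these genes responded in cells, so the test cannot decide on a shared response.

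The 8 genes named as highest in untreated tumours over D0 all had negative ZAC differences, which led to the hypothesis that ZAC tumours lay nearer to cultured cells. To keep the vehicle tumours from entering both sides, genes were taken by the mean of all 11 tumours. Of 313 genes at least 2 above D0, 279 were lower in ZAC tumours, by -0.42 on average (exact permutation p = 0.0108), and of 204 at least 2 below D0, 70 were lower, with a mean of 0.10 (exact permutation p = 0.552). The difference of both means was -0.52 (exact permutation p = 0.0758), which missed the threshold. The 8 genes that led to the hypothesis are among the 313, and this partly restates them; without them the mean was -0.41 over 305 genes, 271 of them lower (exact permutation p = 0.0108), and the difference of both means -0.51 (exact permutation p = 0.0779). The test was run on the same tumours, so the hypothesis stays open.

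Other splits of the tumours show what chance gives. Of 100 splits drawn, the real one included, 8 gave as many genes at an unadjusted p under 0.05 as the real 1576, and the highest other gave 3180. For lists called by camera, 17 of the 100 gave at least the real 11, and the highest other gave 15. Chance was excluded for neither count. At an adjusted p under 0.05 the real count was 0, so all 100 splits had to give at least as many (highest other 5), and that comparison says nothing about chance.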
